A study of Mus musculus with 8 samples.

How the data were processed

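Chromatin accessibility was measured by mtscATAC-seq, single-cell ATAC-seq (a transposase cuts open chromatin and tags the cut ends) done so that mitochondrial DNA is kept in the cell. The 8 libraries came from mouse small intestine, from epithelium taken up with EDTA and TrypLE, stained for CD45, CD31, TER-119 and CD326 and sorted, then fixed with formaldehyde and run on a 10x Chromium, per the labels' protocols. The full sort gate is not given in the sources used here. The deposited values are counts per peak and cell barcode, made with Cell Ranger ATAC 2.1.0 on genome build mm10, per the submitters' processing notes. The matrix headers name the same program. Peaks were called in each library separately, since each deposited peak list differs, so a place with no peak in a library has no count there. Values were whole numbers. No mitochondrial genotype per cell was used here.

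Groups, ages in weeks and mutation loads were read from the labels. The TrnA group had 5 libraries, ND5 had 2 and wild type had 1. The labels name no animal, sex or batch, so p-values rest on differences between these libraries, which may be technical. Replicate numbers were given in accession order and pair nothing.

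Barcodes with at least 1000 counts in peaks were kept, 70244 of 73826 deposited barcodes. Counts in peaks summed to between 41693981 and 251222244 per library. The peak lists merged into 265499 regions. The gene table was the RefSeq table of GRCm38.p6, the assembly that mm10 names. It held 21887 protein-coding genes on chromosomes 1 to 19, X and Y. As a check of the build in the ND5 3-week library, 65.0% of genes had a peak within 1 kb of a gene end and 36.6% had one after gene ends were shifted. A gene's count was the sum over the peaks that overlap its body or the 2 kb either side. The table carries no strand, so the planned window of 2 kb upstream became 2 kb on either side, and the planned promoter alternative could not be set. Peaks within 1 kb of either gene end took its place. Genes whose windows share peaks share counts, and such partners are named in the report.

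Cells were clustered on the 105345 merged regions with a peak in every library, by term frequency weighting, 30 components without the 1 tied to depth, 20 neighbours and Leiden at resolution 1, which gave 29 clusters. A cluster was named from markers fixed before the data were examined. The thresholds for a name were set after seeing the data. They were a median log2 fold of at least 0.4 over the list, against all other clusters pooled, and at least 3 markers raised 1.5-fold. Clusters under those thresholds stayed unnamed. So did a cluster whose 10 leading genes held more markers of another type. A cluster with few counts per cell for its library and no own marker among those genes stayed unnamed too. By these 2 rules cluster 20 (1302 cells, enterocyte list, 0.58, 7 of 14 markers raised) stayed unnamed though it met the thresholds. The same holds for cluster 23 (928 cells, T cell list, 1.06, 8 of 12). Scrublet called 4.21% and 3.14% of cells in 2 libraries and under 0.2% in the others, so it had not worked and no doublets were removed. Leaving out the 5% of cells with the most counts was tried in its place for the shares of cells only, where no call changed.

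For each library, counts were summed over all kept cells and over enterocyte-like, goblet-like and stem-like cells. Each sum was tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr) in R 4.3.3, with genotype and log2 age as terms and 4 residual degrees of freedom. The difference in age slope between ND5 and TrnA was an added term, with 3. Only TrnA at 25 weeks had 2 libraries of the same genotype and age. The residual spread therefore also holds departures from a straight line in log2 age. Without the added term it also holds departures from equal slopes of ND5 and TrnA. These cannot be told apart from differences between like libraries. The age coefficient is a log2 change per doubling of age. The p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, and errors are standard errors. Tests were checked on simulated counts at these depths. Genes were drawn independently at the dispersion fitted to their level, without gaps from missing peaks or other structure of the samples. The shares recovered hold for such counts only and may be lower in the data. In all cells, 78.0% of genes given an age slope of 0.3 and 90.0% of those given 0.6 were recovered, while 19 genes that were given no change were called among 18341. For TrnA against wild type, 54.5% of changes of 1 and 81.0% of changes of 2 on the log2 scale were recovered, and for ND5 against TrnA 72.0% and 87.9%. Genes given no change that were called numbered 5 and 12 in these comparisons. The false calls came beside 99 or 100 genes simulated at each size of change, more than the data called. Their number therefore does not carry over to the 5, 2 and 0 genes called in the data. These few calls can still be false.

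The 36 gene lists were fixed before the data were examined. They cover markers of 12 cell types, proximal and distal small intestine, suckling and adult enterocytes, proliferation and Wnt targets, 5 mitochondrial lists (oxidative phosphorylation, ribosome, tRNA synthetases, biogenesis and quality control, unfolded protein response), the integrated stress response, glycolysis, fatty acid oxidation, cholesterol synthesis, NRF2, 2 interferon lists, NF-kB, antimicrobial genes, p53, senescence, Hox genes and the circadian clock. Each was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01. For the age trend, TrnA against wild type and ND5 against TrnA no list passed with the correlation estimated from the data, and that adjusted p stands beside each list that passed. With single libraries left out, lists were tested at the preset correlation only.

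The genes named were chosen by a rule fixed beforehand. Among genes that passed and lay above the median level, up to 10 with the largest coefficient were taken in each direction, passing over predicted genes and, of genes that share most of their counts, all but the first. Where fewer than 3 passed, the 3 with the smallest p are given. Up to 4 members with the smallest p were taken from each list that passed or had called members. Some genes that the rule names are not reported here. Where a count was 5 or fewer, the genes outside the rule were added after their values were seen. Age results within enterocyte-like, goblet-like and stem-like cells were given their own place after the data were seen. The within-class genotype fits gave few calls and enter as alternatives.

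Alternatives tried were other size factors, no low-count filter, DESeq2 1.42.0, linear age, regions with a peak in all libraries, other cell filters, thinning to the smallest library, single classes, subsets of libraries and each library left out. Shares of cells carry exact Clopper-Pearson 95% intervals and were set against log2 age by exact permutation over the 8 libraries. Intervals cover counting error only.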

Results

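Small-intestinal epithelial cells were profiled from mice that carry a mutation of mitochondrial DNA and from a wild-type mouse. The mutations lie in TrnA, the mitochondrial gene of the alanine tRNA, and in ND5, a subunit gene of respiratory complex I. TrnA libraries came at 3 weeks (load 79%), 25 weeks (78% and 80%), 55 weeks (82%) and 100 weeks (84%). ND5 libraries came at 3 and 100 weeks (both 70%), and the wild-type library at 25 weeks. The series title names mitochondrial DNA mutation and acute colitis, and the labels of these libraries name no treatment. Kept cells, summed counts and median counts per cell were 6317, 179397770 and 28143 for TrnA at 3 weeks. They were 5729, 139533355 and 21951 for the 25-week TrnA replicate 1, and 4434, 82495300 and 14283 for replicate 2. TrnA at 55 weeks gave 10462, 78770436 and 5404, and at 100 weeks 17337, 251222244 and 11866. The wild type gave 5832, 85552009 and 10682. ND5 gave 6434, 41693981 and 4698 at 3 weeks, and 13699, 196372152 and 13516 at 100 weeks. The ND5 3-week library was the shallowest in total and alone lacked any count in 233 genes, against 3 in ND5 at 100 weeks.

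Enterocyte-like, goblet-like and stem-like cells made up most of the named cells, with enteroendocrine-like, Paneth-like, tuft-like and a few T cell-like cells. The 3-week libraries stood apart from each other: enterocyte-like cells were 19.4% (95% interval 18.4 to 20.4) of cells in TrnA and 54.4% in ND5, and goblet-like cells were 33.5% of cells in TrnA. Stem-like cells were 36.1% and 23.8% there. In the older libraries enterocyte-like cells ran from 27.3% (ND5, 100 weeks) to 48.3% (wild type). The top of this range depends on cluster 20, left unnamed though raised in enterocyte markers. It held 757 cells of TrnA 25-week replicate 1 and 109 of the wild type. Paneth-like cells were 4.42% in TrnA and 3.58% in ND5 at 100 weeks and between 0.446% and 1.46% in the other libraries. No class share passed against log2 age over the 8 libraries (7 classes, exact permutation, two-sided). Pearson's r was -0.24 for enterocyte-like cells (p = 0.555, adjusted 0.555, Spearman's rho -0.37, p = 0.363) and 0.58 for Paneth-like cells (p = 0.0952, adjusted 0.333, rho 0.48, p = 0.231). It was -0.42 for goblet-like (p = 0.346, adjusted 0.439), -0.65 for stem-like (p = 0.0780, adjusted 0.333), -0.42 for enteroendocrine-like (p = 0.376, adjusted 0.439), -0.46 for tuft-like (p = 0.251, adjusted 0.439) and 0.40 for T cell-like cells (p = 0.323, adjusted 0.439), with rho of 0.19 (p = 0.657), -0.32 (p = 0.438), 0.25 (p = 0.551), -0.28 (p = 0.485) and 0.37 (p = 0.363). Without the 2 libraries farthest in age, those at 3 weeks, r was -0.94 for enterocyte-like and 0.95 for Paneth-like cells, and 0.97, 0.72, 0.65, -0.12 and -0.55 for the others in that order. Without the TrnA 3-week library alone, the enterocyte-like share passed (r = -0.93, adjusted p = 0.017). Unnamed clusters held 1.9% and 4.2% of cells in the TrnA and ND5 3-week libraries and between 22.6% and 33.8% in the others, which these shares depend on. Each 3-week library also filled its own clusters: cluster 21 held 93.5% of enterocyte-like cells of TrnA, and cluster 9 held 84.7% of those of ND5. In older libraries clusters 1, 2, 3 and 6 held most of the class. Stem-like cells were 85.9% cluster 14 in the TrnA and 95.4% cluster 16 in the ND5 3-week library, against clusters 7, 8 and 13 in older libraries. In these classes a change with age within a cell type and a difference in which cells took the name cannot be told apart.

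**Figure D1:**
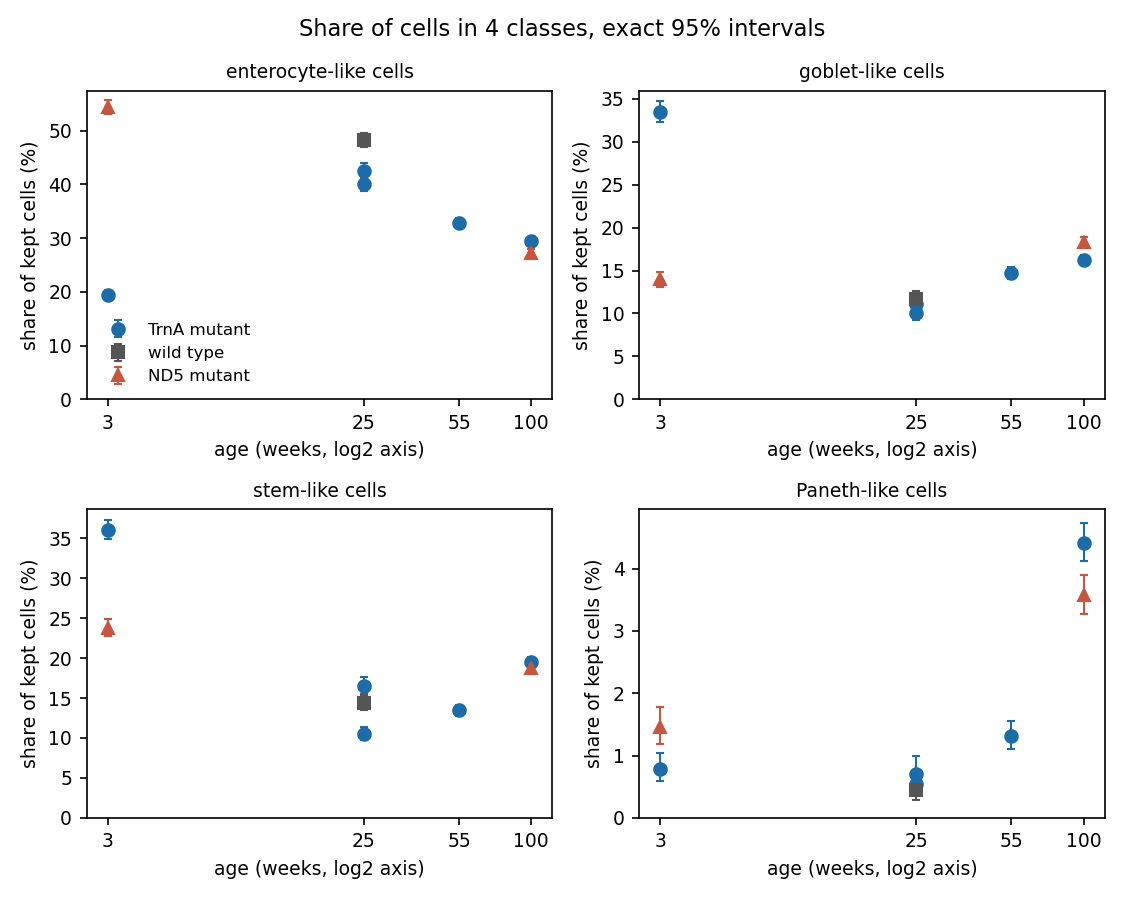
Share of kept cells in 4 classes (y axis, percent) against age in weeks (x axis, log2) for each of the 8 libraries, with exact 95% intervals that cover counting error only. The 3-week libraries lie at 19.4% (TrnA) and 54.4% (ND5) for enterocyte-like cells, and the 100-week libraries at 4.42% and 3.58% for Paneth-like cells.

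The age comparison asks which genes gain or lose accessibility from 3 to 100 weeks in the TrnA and ND5 libraries. The wild type, 1 library at 1 age with its own term, adds nothing to the slope. Ageing without a mutation was therefore not measured. Mutation load was not a term of the model. Among TrnA libraries it was highest at 55 and 100 weeks (82% and 84%), so age and load cannot be fully told apart there. In ND5 it was 70% at both ages. Without the 3-week libraries ND5 is left with 1 library and adds nothing to the slope either. The slope then rests on the older TrnA libraries, so calls lost there cannot tell an absent trend from too few libraries. Over all cells, Dapk1, a calmodulin-dependent kinase (chromosome 13, 60601723 to 60763191), fell by 0.97 ± 0.05 on the log2 scale per doubling of age (n = 8 libraries fitted, adjusted p = 0.00225). Its level went from 131 CPM at 3 weeks to 3.53 CPM at 100 weeks in TrnA, and from 67.8 to 3.10 CPM in ND5. Pdgfd, a platelet-derived growth factor, fell by 0.92 ± 0.07, and Asxl3, a Polycomb-associated gene, fell by 0.62 ± 0.05. Nrn1, which encodes neuritin, fell by 0.42 ± 0.04, and the nuclear receptor gene Rorb fell by 0.35 ± 0.03. Of 18435 genes tested, these 5 passed and none rose. Without an adjustment 1351 had p under 0.05, and DESeq2 called 866. The matrix metalloproteinase gene Mmp2, which shares counts with Lpcat2, came closest upward at 0.42 ± 0.04, which did not pass (adjusted p = 0.0509), and Nell1 (0.26) did not pass either. Without the 3-week libraries 0 genes passed, and Dapk1, with a slope of -1.03, did not pass either (adjusted p = 0.622, range over its alternatives 5.99e-84 to 0.622). With peaks within 1 kb of a gene end 0 passed, and on regions with a peak in all libraries 30 did. The count was 2 without the TrnA 25-week replicate 1 or 100-week library, 3 without the ND5 3-week library and 10 without the wild type.

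The list of MHC class II and interferon gamma targets rose with age over all cells: 17 of 18 members had positive slopes, with a median of 0.070 (adjusted p = 3.19e-14). The call was lost otherwise (adjusted p = 0.656 with an estimated correlation). No member passed over all genes and 6 rose adjusted over the list alone. Among these were H2-Ab1 (0.26), H2-Aa (0.43), both chains of class II molecules, and the peptide-loading genes H2-DMb1 (0.44) and H2-DMb2 (0.52), which share peaks. Markers of B cells (median -0.044), myeloid cells (0.039) and T cells (0.034) did not pass, with adjusted p of 0.831, 0.342 and 0.433. T cell-like cells, however, were 0% (TrnA) and 0.031% (ND5) of cells at 3 weeks. In the older libraries they were between 0.197% (ND5, 100 weeks) and 1.26% (TrnA, 55 weeks). Of the 36 lists, no other passed over all cells, where 2 passed without the TrnA 100-week library, 6 without the TrnA 3-week, 8 without the ND5 3-week and 10 without the ND5 100-week library. Without both 3-week libraries the class II list did not pass (median 0.039, adjusted p = 0.975, range over its alternatives 3.50e-24 to 0.989). There the enterocyte (-0.15, adjusted p = 0.00137), distal (-0.24, adjusted p = 0.00158), suckling (-0.11) and adult enterocyte lists (-0.16) fell and proliferation genes rose (0.065), the last 3 with adjusted p = 0.0444. None of these 5 passed with an estimated correlation (adjusted p = 0.904 for each). For older mice against 3 weeks the NF-kB list was higher (0.13, adjusted p = 0.00251) and goblet markers were lower (-0.34, adjusted p = 0.00657), and neither passed with an estimated correlation (adjusted p = 0.864 for each). The 5 mitochondrial lists had medians from 0.0035 (tRNA synthetases) to 0.021 (unfolded protein response).

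Median slopes of the lists that did not pass over all cells, with adjusted p from 0.111 to 0.899, were as follows. Among markers they were stem (0.0091), enterocyte (-0.019), goblet (-0.062), Paneth (-0.050), enteroendocrine (-0.039), tuft (0.047), endothelial (-0.0054), fibroblast (-0.094) and erythroid cells (0.056). Lists of tissue state had proximal (-0.0090), distal (-0.027), suckling (-0.039), adult (-0.019), proliferation (0.0020), Wnt targets (0.0083), Hox genes (0.018) and circadian genes (0.0058). Metabolic and mitochondrial lists had oxidative phosphorylation (0.011), mitochondrial ribosome (0.012), biogenesis (0.012), glycolysis (0.0050), fatty acid oxidation (0.0011) and cholesterol synthesis (0.0091). Stress and defence lists had integrated stress response (0.0020), NRF2 (0.014), type I interferon (0.0093), NF-kB (0.016), antimicrobial (0.025), p53 (0.0095) and senescence (0.0045). The mean or the direction of the test had another sign than the median for the stem, endothelial, distal, proliferation, tRNA synthetase, stress response, senescence and Hox lists.

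Of the genes that passed within enterocyte-like cells, the class II genes Cd74, H2-Aa and H2-DMb2 (0.55) rose most. Cd74, the invariant chain that guides class II assembly (chromosome 18, 60803849 to 60812652), rose by 0.97 ± 0.17 per doubling of age (adjusted p = 0.0495). It lay at 3.08 CPM (TrnA) and 5.39 CPM (ND5) at 3 weeks and between 79.2 and 149 CPM in the 6 older libraries. H2-Aa (chromosome 17, 34282744 to 34287823) rose by 0.61 ± 0.10 and H2-Ab1 by 0.37 ± 0.05. Older libraries against 3 weeks, a comparison chosen after the data were seen, gave these differences: Cd74 4.92 ± 0.32 on the log2 scale (adjusted p = 0.000375), H2-Aa 3.02 ± 0.27 (adjusted p = 0.00125), H2-DMb2 2.75 ± 0.21 (adjusted p = 0.000450, sharing counts with H2-DMb1), H2-Eb1 1.79 ± 0.19 (adjusted p = 0.00352) and H2-Ab1 1.75 ± 0.20 (adjusted p = 0.00443). The glutamate receptor gene Grik3 (0.29), Gas7 (0.28), Adgrd1 (0.27), Tfap2a (0.21) and Gtpbp4 (0.17) rose too. Cacna2d3, a calcium channel subunit gene, fell by 0.46 ± 0.07, and Igf2bp3, an RNA-binding gene of fetal tissue, fell by 0.38 ± 0.04, from 140 and 171 CPM at 3 weeks to at most 48.5 CPM later. Agbl4, which shares counts with Bend5, fell by 0.37, and the sialyltransferase gene St3gal1 fell by 0.36. Cpne8 (-0.34), Ldlrad3 (-0.30), Hmgxb3 (-0.27, sharing counts with LOC108168367), Timm23 (-0.25), Arhgap10 (-0.25) and Cpvl (-0.23) also fell. In all, 15 genes rose and 80 fell of 18166. DESeq2 called 606.

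Cd74 and H2-Aa did not pass with RLE factors, without the low-count filter, or without the TrnA 3-week, 55-week, 25-week replicate 1, ND5 3-week or ND5 100-week library, and over its alternatives the adjusted p of Cd74 ranged from 3.70e-06 to 0.944. With 1 library left out, the slope of Cd74 ranged from 0.74 to 1.09. The class II list rose in these cells, with 17 of 18 members positive and a median of 0.075 (adjusted p = 7.39e-13). This call did not hold otherwise (adjusted p = 0.745 with an estimated correlation). Of its members 4 rose over all genes and 7 adjusted over the list alone. The suckling enterocyte list fell (median -0.057, adjusted p = 0.0164), and not so otherwise (adjusted p = 0.854 with an estimated correlation). It had 0 members past the test over all genes and 4 adjusted over the list alone: Glb1 (-0.10, sharing counts with Tmppe), Dab2 (-0.17), Prdm1 (-0.099), a repressor of the adult programme, and the neonatal Fc receptor gene Fcgrt (-0.11). The p53 list rose (median 0.034, 14 of 16 members positive, adjusted p = 0.0212), a call lost too (adjusted p = 0.745 with an estimated correlation). Eda2r, a death-receptor gene, led it with 0.50 ± 0.10 and rose adjusted over the list alone (adjusted p = 0.0110). The count of 95 genes became 13 without the TrnA 3-week library, 8 without the ND5 3-week library, 11 without the ND5 100-week library and 3 without both 3-week libraries. It was 60, 59 and 56 without the TrnA 55-week, 25-week replicate 1 and 100-week libraries.

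**Figure D2:**
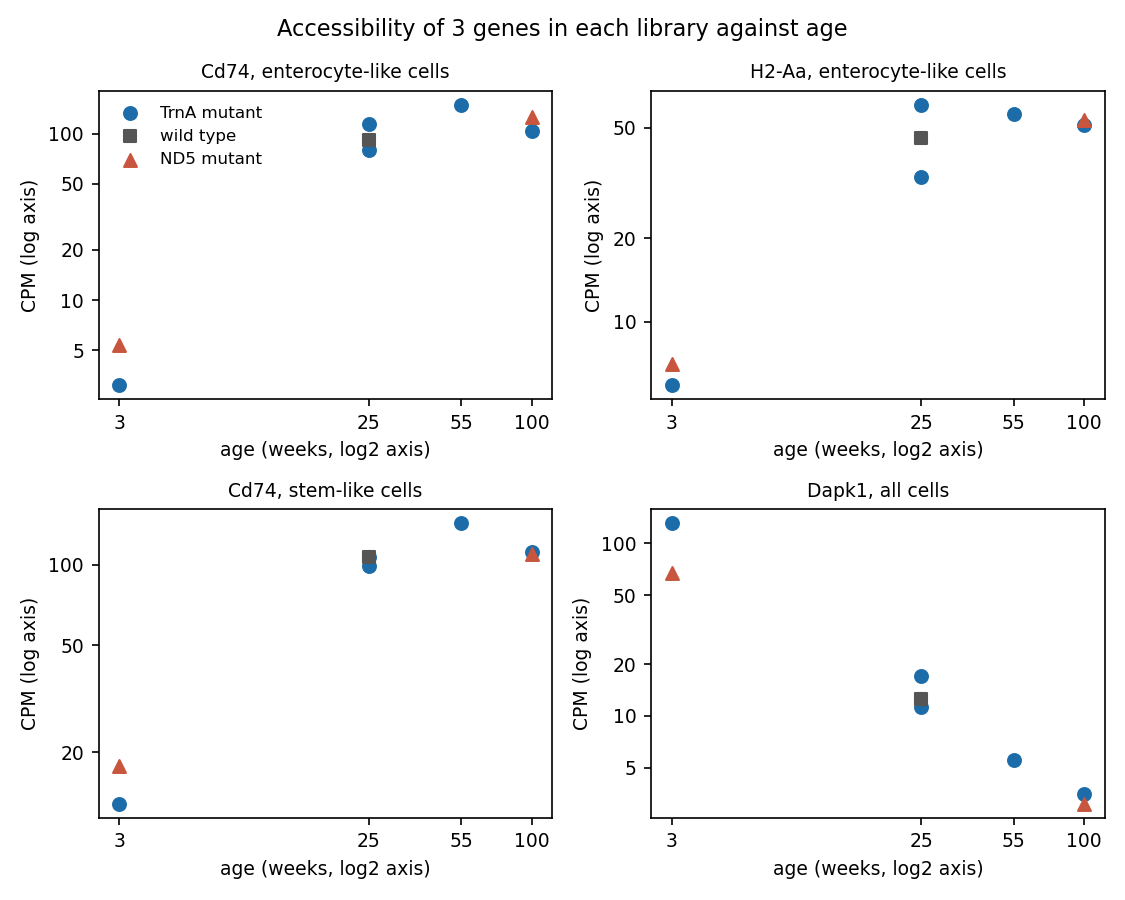
Accessibility in CPM, counts scaled to the size of each library (y axis, log scale), of Cd74 and H2-Aa in enterocyte-like cells, Cd74 in stem-like cells and Dapk1 in all cells, against age in weeks (x axis, log2), 1 point per library. Cd74 in enterocyte-like cells lies at 3.08 and 5.39 CPM at 3 weeks and at 79.2 CPM or more in every older library, and Dapk1 ends at 3.53 and 3.10 CPM at 100 weeks.

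In goblet-like cells, Nrxn3, a synaptic adhesion gene, rose by 0.56 ± 0.07 per doubling of age (adjusted p = 0.0239), and Cacna1e (0.25) and Gas7 (0.25) rose with it. Dapk1 fell by 1.17 ± 0.08, Asxl3 fell by 0.63 ± 0.06, Usp29 fell by 0.49 and Prickle2, a planar polarity gene, fell by 0.32. Igf2bp3 (-0.20), Rbms1 (-0.20) and the laminin gene Lamc1 (-0.19) fell as well. Dapk1, Asxl3 and Prickle2 are also among the leading genes of cluster 22, a goblet-like cluster of mostly TrnA 3-week cells. In all 7 genes rose and 31 fell of 17621, and DESeq2 called 269. The class II list rose (median 0.044, adjusted p = 1.31e-11, and adjusted p = 0.195 with an estimated correlation), with 0 members past the test over all genes and 8 adjusted over the list alone, Cd74 (0.62) and H2-Aa (0.32) among them. The count of 38 was 7 on regions with a peak in all libraries, 0 without the 3-week libraries, and 7, 24, 6 and 9 without the TrnA 3-week, 25-week replicate 1, 100-week and 25-week replicate 2 libraries.

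In stem-like cells Cd74 rose by 0.60 ± 0.10 (adjusted p = 0.0417) and the interferon-responsive gene Sp100 rose by 0.37 ± 0.06, from 20.1 and 20.4 CPM at 3 weeks to at least 65.2 CPM later. Khdrbs3 (0.32), Dnase2b (0.31), H2-Ab1 (0.31), Cacna1e (0.29), Tmem132c (0.28), Ppp2r1b (0.28), Gas7 (0.28) and Map9 (0.27) rose. The potassium channel gene Kcnt2 fell by 0.95 ± 0.15, the calcium channel gene Cacnb2 fell by 0.33 ± 0.02, Cpne8 fell by 0.32 and the adenylate cyclase gene Adcy8 fell by 0.29. Fras1 (-0.24), St3gal1 (-0.22), Sfrp2 (-0.22), Macroh2a1 (-0.19), Clic6 (-0.18) and Igf2bp3 (-0.17) fell as well. In all 42 genes rose and 57 fell of 17973, and DESeq2 called 1244.

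In these cells the class II list rose (median 0.080, adjusted p = 1.99e-15, and adjusted p = 0.361 with an estimated correlation), with 5 members past the test over all genes and 7 adjusted over the list alone. For older mice against 3 weeks it also passed with an estimated correlation (17 of 18 members, median 0.41, adjusted p = 0.0297, range over its alternatives 1.26e-38 to 0.928). Over all cells, in enterocyte-like and in goblet-like cells it did not (adjusted p of 0.0986, 0.0947 and 0.116). Absorptive genes fell: the enterocyte list had 14 of 14 members negative (median -0.079, adjusted p = 3.08e-05, and adjusted p = 0.649 with an estimated correlation), with Apoa1 (-0.11) past the test adjusted over the list alone. Most stem-like cells of the 3-week libraries came from clusters 14 and 16, which held few of the older cells. Cluster 14 had 4 of 10 stem markers raised. A change within stem cells and a difference in which cells took the name cannot be told apart. The distal list fell (adjusted p = 0.000207, and adjusted p = 0.380 with an estimated correlation), led by the bile acid transporter gene Slc51a, which fell by 0.31 ± 0.03. The proximal list fell (adjusted p = 0.00902, and adjusted p = 0.673 with an estimated correlation), as did the suckling list (adjusted p = 0.000387, and adjusted p = 0.361 with an estimated correlation), both with the lactase gene Lct (-0.36), which did not pass over all genes (adjusted p = 0.108). Without the 3-week libraries Lct (0.23) and Apoa1 (0.033) went the other way, and none of these lists passed. The adult enterocyte list fell (adjusted p = 0.000667, and adjusted p = 0.689 with an estimated correlation) with the glucose transporter gene Slc2a2 (-0.14). Wnt targets rose (adjusted p = 0.00650, and adjusted p = 0.817 with an estimated correlation) with Nkd1 (0.17), and tuft markers rose (adjusted p = 0.0457, and adjusted p = 0.689 with an estimated correlation). The hexokinase gene Hk1 (0.18) and Eda2r (0.38) rose while their lists, glycolysis and p53 targets, did not pass. Other glycolysis genes had negative slopes with 1 library left out in turn. These were Pfkm (-0.11 to -0.073), Pfkp (-0.12 to -0.055) and Pkm (-0.065 to -0.036). Of the p53 list Sesn1 stayed negative (-0.11 to -0.044), and Bbc3 (0.012 to 0.12) and Perp (0.012 to 0.11) stayed positive. The count of 99 was 4 without the TrnA 3-week library, 0 without the ND5 3-week library, 7 without the ND5 100-week library, 0 without both 3-week libraries, and 320, 26 and 15 without the TrnA 55-week, 25-week replicate 1 and 25-week replicate 2 libraries.

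Set against the 1 wild-type library, TrnA libraries were higher in 2 genes and lower in 0. Gamt, an enzyme gene of creatine synthesis (chromosome 10, 80258151 to 80261025) that shares counts with Dazap1, had 0 CPM in wild type and 53.8 to 90.2 CPM in TrnA (adjusted p = 0.0190). Cd14, a lipopolysaccharide co-receptor gene (chromosome 18, 36725064 to 36726815), had 0 CPM against 10.0 to 13.9 CPM (adjusted p = 0.00576). No fold is given, since a library has no counts where its list holds no peak. Every call here rests on the 1 wild-type library. On regions with a peak in all libraries, which leave both genes out by construction, 0 passed. Without the TrnA 55-week library 0 passed, without 25-week replicate 1 there was 1, and with peaks near gene ends there were 15. Of 18435 genes 136 had p under 0.05, and DESeq2 called 341. Prkd3, Tal1, Slc6a17 (-0.55), Nkain3 (-1.06) and Stc2 did not pass.

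Hox genes as a list were higher in TrnA (34 of 38 members, median 0.31, adjusted p = 0.000160, and adjusted p = 0.209 with an estimated correlation), with 0 members past the test over all genes or adjusted over the list alone. Of its members 4 had 0 counts in wild type, and the median without them was 0.28. The list did not pass near gene ends (median 0.25, adjusted p = 0.208), in goblet-like cells (0.087, adjusted p = 0.686) or in stem-like cells (0.10, adjusted p = 0.179), and over its alternatives the adjusted p ranged from 2.84e-05 to 0.686. Examples are Hoxd9 (1.25 ± 0.53), Hoxa6 (1.13, sharing counts with Hoxa3 and Hoxa5) and Hoxb3 (0.42). The enterocyte list was lower (14 of 14 members, median -0.18, adjusted p = 0.00774, and adjusted p = 0.943 with an estimated correlation), with Alpi (-0.46), Fabp1 (-0.37) and Mep1a (-0.25), and its median was -0.0069 without the TrnA 3-week library. Within enterocyte-like cells it did not pass (median -0.11, adjusted p = 0.165), nor near gene ends (-0.17), and over its alternatives the adjusted p ranged from 0.000832 to 0.943. The wild-type library had the highest enterocyte-like share of the older libraries, 48.3%, with cluster 20 left unnamed. That cluster, raised in enterocyte markers, held 757 cells of TrnA 25-week replicate 1 and 109 of the wild type. Counted as enterocyte-like, it would put that TrnA library first. Without the ND5 100-week library 8 lists passed. Proliferation genes were higher (16 of 20, median 0.11, adjusted p = 0.0288, and adjusted p = 0.943 with an estimated correlation), with Cdk1 (0.38) and Mki67 (0.20). Without the TrnA 55-week or 100-week library this list did not pass, with medians of 0.069 and 0.10, nor did it near gene ends (adjusted p = 0.208) or in enterocyte-like (0.165), goblet-like (0.952) and stem-like cells (0.179), with a range over its alternatives of 0.00894 to 0.952. The T cell list was higher (adjusted p = 0.0288, and adjusted p = 0.943 with an estimated correlation), but 5 of 12 members had 0 counts in wild type and the median of the other 7 was -0.015. The integrated stress response list had a median of 0.11 and a mean of -0.095 and did not pass (adjusted p = 0.0506). No mitochondrial list passed. Within enterocyte-like cells the stress response list did pass (22 of 28 members higher, median 0.19, adjusted p = 0.00772, and adjusted p = 0.842 with an estimated correlation), with 0 members past the test over all genes or adjusted over the list alone.

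ND5 against TrnA gave 0 genes by edgeR of 18435 tested, 286 with p under 0.05 and 106 by DESeq2. Mutation load was 70% in the ND5 libraries and 78% to 84% in TrnA, so the mutation and its load cannot be told apart here. Best1 (0.93 ± 0.14), Necab1 (1.03) and Acsl6 (0.56) had the smallest p among genes higher in ND5, and Limch1 (-0.78), Cacna1e (-0.65) and Fzd3 (-0.70) among those lower, and none of them passed. Lists differed where single genes did not. The proximal small intestine list was higher in ND5 (12 of 12 members, median 0.36, adjusted p = 8.36e-08, and adjusted p = 0.472 with an estimated correlation), with Creb3l3 (0.33 ± 0.13) and Onecut2 (0.42). Fatty acid oxidation genes were higher (19 of 19, median 0.12, adjusted p = 1.09e-06, and adjusted p = 0.472 with an estimated correlation), with Angptl4 (0.47) and Acaa2 (0.30). Adult enterocyte genes were higher (8 of 8, median 0.27, adjusted p = 0.00358, and adjusted p = 0.825 with an estimated correlation), with Tmprss15 (0.67) and Slc2a2 (0.34). Without the ND5 3-week library these medians were 0.0049, -0.0035 and -0.23, and without the TrnA 3-week library the adult enterocyte median was 0.0064. Enterocyte-like cells were 54.4% of that ND5 library and 19.4% of its TrnA counterpart.

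Hox genes were lower in ND5 (33 of 38, median -0.35, adjusted p = 2.26e-06, and adjusted p = 0.132 with an estimated correlation), with Hoxb3 (-0.58 ± 0.15) and Hoxd3 (-0.44), which shares peaks with Hoxd4. Within enterocyte-like cells the Hox list did not pass (median -0.18, adjusted p = 0.357, range over its alternatives 9.31e-07 to 0.357). The class II list was lower in the fitted model (18 of 18, median -0.23, adjusted p = 0.000282, and adjusted p = 0.825 with an estimated correlation), with H2-Aa at -0.47 ± 0.29. At matched ages H2-Aa hardly differed, with 9.78 CPM in TrnA and 9.58 in ND5 at 3 weeks and 42.7 and 40.1 at 100 weeks. H2-DMb2, fitted at -0.47, had 3.97 and 3.78, then 22.3 and 22.9 CPM. Lower in ND5 at both ages were Psmb8 (30.1 and 24.6, then 43.7 and 30.3 CPM) and Gbp3 (10.7 and 10.2, then 13.9 and 12.6 CPM). ND5 has no library at 25 or 55 weeks, so the fitted difference depends on a straight line in log2 age. Type I interferon targets were lower (median -0.12, adjusted p = 0.0343, and adjusted p = 0.825 with an estimated correlation), as were enteroendocrine markers (median -0.24, adjusted p = 0.0343, and adjusted p = 0.825 with an estimated correlation), with Isl1 (-0.96) and Rfx6 (-0.40). Without the ND5 3-week library the enteroendocrine median was -0.017 (adjusted p = 0.928) and without the TrnA 3-week library -0.14 (adjusted p = 0.642), and over its alternatives the adjusted p ranged from 0.0111 to 0.928. Enteroendocrine-like cells were 7.47% of the TrnA and 1.54% of the ND5 3-week library. In none of these lists did a member pass, over all genes or adjusted over the list alone. Without the ND5 100-week library the class II median was -0.097, type I interferon 0.15 and Hox -0.30, none passing, and 13 single genes were lower in ND5. Without the TrnA 3-week library 1 gene passed. The distal list had a median of -0.023 and a mean of -0.36 and did not pass.

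**Figure D3:**
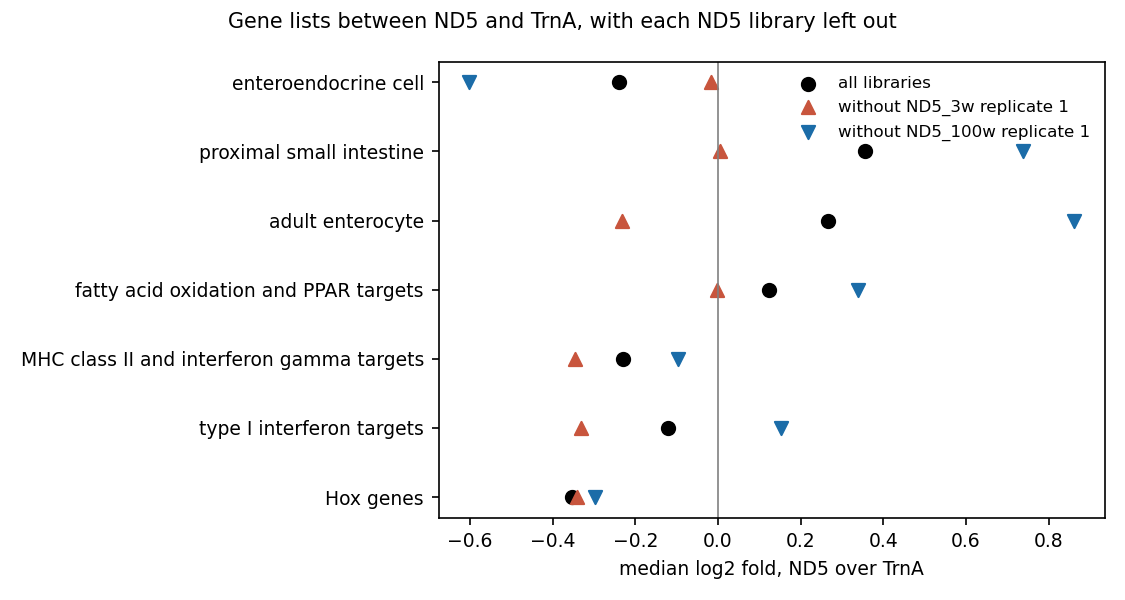
Median log2 fold of ND5 over TrnA (x axis) for the 7 gene lists that passed at the preset correlation (y axis), with all libraries and with each ND5 library left out. The proximal list moves from 0.36 to 0.0049 without the ND5 3-week library, and the Hox list stays between -0.35 and -0.30.

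The age slope of ND5 set against that of TrnA asks whether the genotypes age differently. Over all cells 0 of 18435 genes passed by edgeR, with 1323 at p under 0.05 and 786 called by DESeq2. Enterocyte-like and stem-like cells gave 0 as well, with 539 and 967 genes at p under 0.05 and 146 and 167 by DESeq2. Goblet-like cells gave 2 of 17621, with 1794 at p under 0.05 and 333 by DESeq2. Nkpd1 differed by 2.28 ± 0.26 and Xirp1, a muscle actin-binding gene, by 0.76 ± 0.08 per doubling of age (both adjusted p = 0.0332), each from low values in the ND5 3-week library, 0 and 4.19 CPM.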

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

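All tests that weigh an explanation here, the orders of ages included, were chosen after the results they bear on had been seen.

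In goblet-like cells the age slopes of ND5 and TrnA differed, by a test of the difference itself, for Nkpd1 (2.28 ± 0.26 on the log2 scale per doubling of age, ND5 minus TrnA) and Xirp1 (0.76 ± 0.08), both with adjusted p = 0.0332. Nkpd1 had 0 CPM in the ND5 3-week library and 14.6 to 22.5 CPM in the others, and Xirp1 had 4.19 against 44.3 to 56.9 CPM. Nkpd1 is 1 of 8 genes that had 0 counts over all cells in 1 mutant library alone and at least 5 CPM in each other library. A peak missing from the list of the ND5 3-week library may account for Nkpd1. For Xirp1 no explanation was tested.

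In enterocyte-like cells the class II list rose with age. Immune cells among the sorted cells were argued against as the whole cause: 17 B cell and myeloid genes had a median change of -0.028 from 3 weeks to older mice, against 0.35 for the list (one-sided permutation of gene labels, p = 0.00977). Differing peak lists were argued against too, since the median slope was 0.071 on regions with a peak in all libraries (adjusted p = 5.83e-13, and adjusted p = 0.456 with an estimated correlation, range over its alternatives 1.81e-31 to 0.863). Without the 3-week libraries the median slope was 0.0094, lower than the 0.075 with all libraries. It then rests on the older TrnA libraries only, so a step between 3 and 25 weeks and a steady trend cannot be told apart. Of 60 orders of the ages over the TrnA libraries 12 gave a median as large (real 0.075, highest other 0.091), so chance is not excluded for a trend over all ages. Of the 12 orders that keep the 3-week library in place 11 were among them, so these orders could not test a step at 3 weeks. For older mice against 3 weeks Cd74 differed by 4.92 ± 0.32 (adjusted p = 0.000375), with means of 111 and 4.23 CPM. Age stays open as untested.

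Both genes called higher in TrnA than in wild type, Gamt and Cd14, had 0 counts in the wild-type library. Such gaps also occurred in mutant libraries: 8 genes had 0 counts in 1 mutant library alone and at least 5 CPM in each other library, 4 of them in the ND5 3-week library. Peaks missing from the list of the wild-type library may therefore account for both calls. A difference of genotype stays open, untested, with 1 wild-type library.

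The proximal list was higher in ND5. Without the ND5 3-week library its median was 0.0049, and without the ND5 100-week library 0.74, so the difference may belong to 1 library. A higher share of enterocyte-like cells there and a difference within these cells cannot be told apart: within enterocyte-like cells the median was 0.20, but of ND5 over TrnA at 3 weeks it was 0.068, with 8 of 12 genes higher (exact sign flip, p = 0.239). Another stretch of the small intestine and the genotype cannot be told apart either: the 10 distal genes had a median ratio of 0.19 on the log2 scale, ND5 over TrnA at 3 weeks, with 2 lower (exact sign flip, p = 0.490).

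For the counts of genes called with age, other orders of the ages over the TrnA libraries were tried, 60 with the real one. As many calls came from 2 orders over all cells (real 5, highest other 5) and from 1 in enterocyte-like cells (real 95, highest other 94). In goblet-like cells 2 orders gave as many (real 38, highest other 457). These 3 shares lie under 0.05 over the 60 orders, but most of the orders move the 3-week library. The orders therefore cannot tell a trend over all ages from a difference of that 1 library, and chance is not excluded. Of the 12 orders with the 3-week library in place 2, 1 and 1 gave as many calls, the real one included. These 12 orders are too few for a share under 0.05. In stem-like cells 4 orders gave as many (real 99, highest other 761), so chance is not excluded there either. In goblet-like and stem-like cells some orders gave several times the real count, which points to a structure of the samples whose cause was not tested.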

How the results depend on the processing

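Tests with peaks within 1 kb of a gene end, goblet-like or stem-like cells, 3 weeks against older mice, all alternatives of the age results within a class, and for lists the shared regions and single libraries left out, were chosen after the data were seen. Of the values of named genes under the alternatives, 2444 kept direction and side of the threshold, 468 no longer passed, 86 newly passed and 36 reversed. For lists these were 120, 49, 0 and 7. Named genes that passed in neither fit count as kept, and only genes that passed in the main fit could stop passing. The 2444 are therefore no measure of how stable the calls were. With linear age, for example, 113 values were kept and 52 no longer passed. The planned promoter window and the removal of Scrublet doublets were not run. No paired analysis was possible because the labels name no animal and the replicate numbers were given in accession order. A library left alone in its genotype is fitted by its own term and adds nothing to the age slope. In comparisons of genotypes it is assumed to vary like the others. Without either ND5 library, or without the 3-week libraries, the age slope therefore rests on TrnA libraries only. Calls lost in these fits cannot tell an absent trend from too few libraries. For every changed result below the cause was not tested.

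The 5 genes called with age became 14 with RLE factors, 866 with DESeq2, 3 with linear age, 0 with peaks near gene ends, 30 on regions with a peak in all libraries, 8 with at least 3000 counts per cell, 17 after thinning, 95, 38 and 99 in enterocyte-like, goblet-like and stem-like cells, 3 in TrnA libraries, 0 without the 3-week libraries and 32 for 3 weeks against older. The 2 genes of TrnA against wild type became 341 with DESeq2, 15 near gene ends, 0 on shared regions (which leave both genes out), 1 in goblet-like cells and 1 in 25-week libraries. ND5 against TrnA went from 0 to 106 with DESeq2. The slope difference went from 0 to 8 with total counts, 786 with DESeq2, 23 near gene ends, 2 after thinning and 2 in goblet-like cells.

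Within enterocyte-like cells the 95 genes became 149 with total counts, 606 with DESeq2, 15 with linear age, 6 in TrnA libraries, 3 without the 3-week libraries and 192 for 3 weeks against older. In goblet-like cells 38 became 269 with DESeq2, 14 with linear age, 7 on shared regions, 25 in TrnA libraries and 0 without the 3-week libraries. In stem-like cells 99 became 1244 with DESeq2, 17 with linear age, 5 in TrnA libraries, 0 without the 3-week libraries and 174 for 3 weeks against older. Lists passing for age went from 1 to 0 with an estimated correlation, 2 near gene ends, 3 in enterocyte-like cells, 2 on shared regions and 8 in stem-like cells. For TrnA against wild type 4 became 0 with an estimated correlation, 1 near gene ends, 0 in goblet-like and 0 in stem-like cells. For ND5 against TrnA 7 became 0 with an estimated correlation.

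For TrnA against wild type the log2 difference reversed near gene ends for Slc6a17 (0.093) and Hoxb3 (-0.12), in enterocyte-like cells for Stc2 (2.21), in goblet-like cells for Alpi (0.43) and Fabp1 (0.53), in stem-like cells for Alpi (0.089), Fabp1 (0.044) and Mep1a (0.049), and in 25-week libraries for Mep1a (0.041). For ND5 against TrnA it reversed for Pax6 in enterocyte-like cells (0.18), Slc40a1 near gene ends (-0.16) and Ifit1 in age-matched libraries (0.059). The median of the enterocyte list reversed in goblet-like (0.15) and stem-like cells (0.047), and that of the T cell list in goblet-like cells (-0.014), with the test's direction reversed on shared regions (0.0075). Without the 3-week libraries the age slope reversed in enterocyte-like cells for St3gal1 (0.016), Hmgxb3 (0.017) and H2-DMb2 (-0.0064), and in stem-like cells for Khdrbs3 (-0.027), Dnase2b (-0.012), Gas7 (-0.017), Apoa1 (0.033), Alpi (0.18), Avil (-0.12), Rgs13 (-0.31), Lct (0.23), Fabp1 (0.19), Clec2h (0.082), Tmprss15 (0.030) and Ascl2 (-0.089). The correlation of shares with age reversed with each library clustered on its own for enterocyte-like (0.30), stem-like (0.17) and tuft-like cells (0.49), at the lower clustering resolution for stem-like cells (0.013) and with linear age for T cell-like cells (-0.0054).

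With each library left out in turn, calls ranged from 2 to 10 for age, 0 to 2 for TrnA against wild type, 0 to 13 for ND5 against TrnA, and, for age, 8 to 99 in enterocyte-like, 6 to 49 in goblet-like and 0 to 320 in stem-like cells. Lists passing ranged from 1 to 10 for age, 3 to 8 for TrnA against wild type and 6 to 8 for ND5 against TrnA. The ND5 minus TrnA difference ranged from -0.98 to 0.039 for Rfx6, -0.0017 to 0.98 for Slc40a1, -0.12 to 0.88 for Slc2a2, -0.26 to 0.95 for Arg2, -0.22 to 0.89 for Sis, -0.60 to 0.19 for Ifit1 and -0.46 to 0.20 for Usp18. List medians ranged from -0.60 to -0.017 (enteroendocrine), -0.23 to 0.86 (adult enterocyte) and -0.33 to 0.15 (type I interferon). The correlation with age ranged from -0.93 to 0.20 for the enterocyte-like share, -0.61 to 0.47 for goblet-like and -0.76 to 0.74 for enteroendocrine-like cells.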
